A study of Mus musculus with 11 samples.

How the data were processed

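Per the labels, mice were immunised with mouse myeloperoxidase and then received a low dose of sheep globulin against mouse basement membrane to start glomerulonephritis. Kidney T cells were sorted 21 days later, with cells of 3 mice pooled for each sort. Sorting on CD4, CD8, CD127 (the IL-7 receptor alpha chain, gene Il7r) and PD-1 (gene Pdcd1) gave 4 populations. Per the labels, RNA was extracted with the Agencourt RNAdvance Cell kit, 2 ng went into single primer isothermal amplification, and 75-base single reads came from a NextSeq550. Each library is a pool of 3 mice, so the spread between libraries is between pools and not between animals. A further CD4+CD127-PD-1+ sample failed quality control per the labels, which left n = 2 for that group and n = 3 for the other 3 groups. The series title names neutralisation of the IL-7 receptor, and animals given that treatment were not analysed here.

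The deposited table holds raw read counts for 46078 genes, which were used as deposited raw counts. Per the submitters' processing notes, STAR, featureCounts and the mouse build GRCm38 were used. Their versions, the gene annotation release and the strand setting are not given in the sources used here. Without a strand setting, reads of overlapping and antisense genes cannot be told apart. Reads of close paralogs and multigene families, such as histone, ribosomal protein and major histocompatibility genes, may be assigned uncertainly. Of the columns in the table, 11 matched the labelled samples and 1 further column without a label was not used. Coordinates were taken from GENCODE M21 (GRCm38), where 45229 of the 46078 identifiers were found.

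Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at its default settings, which left 16365 genes, and library sizes were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model with a mean for each of the 4 groups was fitted to all 11 libraries, and p values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. Normalised counts (CPM, the edgeR unit) use TMM-scaled library sizes and are given as mean ± SD over libraries. Log2 fold changes are model estimates at the default prior count of edgeR, and a prior count of 2 was used only for log2 CPM. The standard errors (SE) of the fold changes are the estimate divided by the square root of the quasi-likelihood F. The common biological coefficient of variation was 0.244. Principal components were computed on log2 CPM of the tested genes.

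The 5 comparisons, the gene lists, the model, the threshold, the alternatives and the rule for naming genes were fixed before the data were examined. The comparisons were CD127-PD-1+ against CD127+PD-1- in CD4 cells (the CD4 state comparison), the same in CD8 cells (the CD8 state comparison), CD4 against CD8 in each state, and the difference between the CD4 and CD8 state changes (state by lineage). The named genes were chosen per comparison as follows. The sort markers Il7r, Pdcd1, Cd4, Cd8a and Cd8b1 were always included. The 5 largest increases and 5 largest decreases (4 and 4 for the comparisons that involve lineage) were taken among called genes with an average log2 CPM of at least 4. They also needed no overlap between the libraries of the compared groups, except for state by lineage. Predicted genes, pseudogenes and antigen receptor segments were left out of this step. For the state comparisons, the 2 called members with the smallest p were taken from the naive, inhibitory receptor, cytotoxic, regulatory, follicular helper, type 1, tissue residency, cell cycle and IL-7 lists and 1 from each other list. For the comparisons that involve lineage, 2 each were taken from the CD4 lineage, CD8 lineage, regulatory, cytotoxic and follicular helper lists. A gene that the rule selects is not reported here and was left out of the named-gene totals. For a list without a called member, its most abundant member was given as a value only. Other genes printed below are members of the fixed lists, given as examples of their list, or of lists of macrophage and plasmacytoid dendritic cell genes that were written after the data were seen.

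The 30 tested lists covered naive, memory and quiescence; inhibitory receptor; cytotoxic effector; regulatory T cell; follicular helper; type 1, type 2 and type 3 helper; tissue residency; cell cycle; T cell receptor stimulation; IL-7 and STAT5; interferon-stimulated; glycolysis; oxidative phosphorylation; ribosomal protein; cytokine; and chemokine receptor and integrin genes. They also covered CD4 lineage, CD8 lineage and pan-T genes, and genes of kidney tubule, endothelium and podocyte, myeloid cells, B and plasma cells, NK and innate lymphoid cells, gamma-delta T and NKT cells, neutrophils, red cells and platelets, and tissue digestion stress. Of 452 distinct list genes 451 were found in the table, 3 of them under another symbol. Members of a list count as called when they pass the genome-wide threshold, and counts adjusted over the list alone are given in the same paragraph where they differ. Lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 30 lists. Camera with an estimated correlation and fry were run as alternatives. Genes of a list are not independent replicates. Some genes stand in several lists, so the lists are not independent of each other either.

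The alternatives were an adjusted p under 0.01, RLE scaling, library totals only, no filter, a strict filter (CPM of 5 in 2 libraries), DESeq2 1.42.0, limma-voom with and without sample weights, and a model on the compared groups only. Further ones were replicate number as a block (by description or by title), counts thinned to the smallest total, mitochondrial, haemoglobin and immunoglobulin genes left out, and each library left out in turn. Scaling without ribosomal RNA and mitochondrial genes and a per-library score of myeloid genes as a covariate were added after the data were seen. With a CD4+CD127-PD-1+ library left out, the lone remaining library of that group is assumed to vary as the other groups do.

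As a self-test, counts of the 11 libraries were simulated from the fitted dispersions with a 2-fold and a 4-fold change in 100 genes each, and recovery was counted in each comparison. In the CD4 state comparison 26% of the 2-fold and 57% of the 4-fold changes were recovered, in the CD8 state comparison 29% and 67%. In the comparison of CD4 with CD8 cells recovery was 23% and 65% in the CD127+PD-1- state and 29% and 67% in the CD127-PD-1+ state. For state by lineage it was 7% and 49%. False calls made up 1.19%, 3.03%, 8.33%, 5.88% and 3.45% of calls in the same order of comparisons. The simulations held 84 and 99 calls in the CD4 and CD8 state comparisons, against 1912 and 2555 in the data. For state by lineage they held 58, against 1 in the data. The Benjamini-Hochberg cut-off depends on the number of calls, so these shares do not measure the power of the real comparisons. Figures and summaries were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.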

Results

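RNA from T cells sorted out of kidneys with glomerulonephritis after immunisation with myeloperoxidase was measured in 4 populations. These were CD4 cells sorted as CD127-PD-1+ (n = 2) or CD127+PD-1- (n = 3) and CD8 cells sorted as CD127-PD-1+ (n = 3) or CD127+PD-1- (n = 3), each library from a pool of 3 mice. Library totals ran from 10.6 M to 16.1 M counts, with group means ± SD of 14.5 ± 0.243 M, 11.3 ± 0.870 M, 15.4 ± 0.613 M and 13.7 ± 1.07 M in the order given. Between 20514 and 21849 genes were detected per library, and 16365 genes were tested.

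Il7r, Pdcd1, Cd4 and Cd8a followed the labels, which checks the labels and is not a finding. Cd8b1 followed them only in part, since it also differed between the CD4 populations. Il7r (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176, GRCm38), which encodes CD127, measured 21.4 ± 8.24 CPM in CD4+CD127-PD-1+ and 385 ± 60.6 CPM in CD4+CD127+PD-1- cells. In CD8 cells it measured 16.1 ± 1.99 and 367 ± 47.8 CPM, with log2 fold changes of -4.17 (SE 0.26, adjusted p = 3.68e-05) in CD4 and -4.51 (SE 0.22, adjusted p = 2.72e-06) in CD8 cells. Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), which encodes PD-1, was higher by 3.41 (SE 0.41, adjusted p = 0.000572) and 3.38 (SE 0.38, adjusted p = 0.000218). Cd4 measured 634 ± 65.2 and 554 ± 61.1 CPM in the CD4 populations against 4.88 ± 4.38 and 6.54 ± 2.68 CPM in the CD8 populations. Cd8b1, a chain of the CD8 receptor, measured 350 ± 59 and 406 ± 42.2 CPM in the CD8 populations and 37.2 ± 20.9 CPM in CD4+CD127+PD-1- cells, against 3.87 ± 2.99 CPM in CD4+CD127-PD-1+ cells (log2 fold change -3.27, SE 0.51, adjusted p = 0.00249). Cd8a measured 0.403 and 1.09 CPM in the CD4 populations and was not called between them (log2 fold change -1.43, adjusted p = 0.287).

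Across all tested genes the libraries grouped by population. The leading principal component held 43.5% of the variance and separated the CD127/PD-1 states, and the next held 18.3% and separated CD4 from CD8 cells. Mitochondrial ribosomal RNA made up 30.8 ± 0.0399%, 29.4 ± 1.37%, 38.9 ± 2.84% and 30.7 ± 1.82% of counts in the 4 populations in the order above. Its share was highest in CD8+CD127-PD-1+ cells (exact permutation p = 0.1 against CD8+CD127+PD-1- cells, the smallest p that 3 against 3 libraries can give). The other mitochondrial genes made up 3.35 ± 0.612% there and 2.00 ± 0.190% in CD8+CD127+PD-1- cells (exact permutation p = 0.1). These shares lie beside every difference between the CD8 populations given below.

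**Figure D1:**
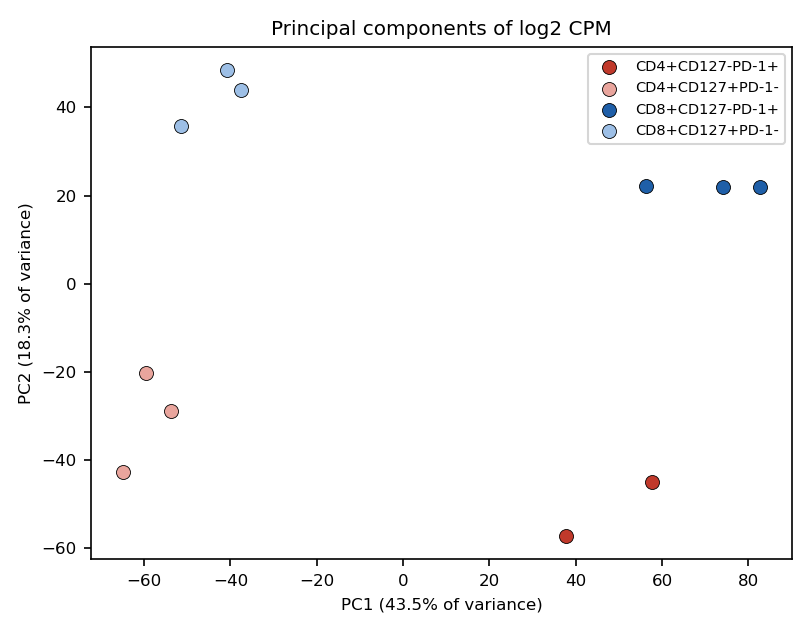
Principal components of log2 CPM over the 16365 tested genes for 11 libraries. PC1 holds 43.5% and PC2 18.3% of the variance, and colours mark the 4 sorted populations.

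In kidney CD4 cells, 18 of 20 measured genes of the naive, memory and quiescence list were lower in the CD127-PD-1+ than in the CD127+PD-1- population and none was higher (19 lower over the list alone; mean log2 fold change -1.95, camera adjusted p = 4.4e-34). The list's adjusted p = 0.0740 with an estimated correlation. Tcf7 (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014), which encodes the transcription factor TCF-1 of naive and memory T cells, measured 98.5 ± 10.3 against 379 ± 70.5 CPM (log2 fold change -1.95, SE 0.16, adjusted p = 0.000122). Satb1, a chromatin organiser of resting T cells, measured 221 ± 25.6 against 1171 ± 68.6 CPM (-2.41, SE 0.22, adjusted p = 0.000122). The lymph node homing gene Ccr7 fell by 2.49, while Btla and Il6ra were not called. Igfbp4, an insulin-like growth factor binding protein of naive T cells, was among the 5 largest decreases under the abundance and no-overlap rule (-3.69, SE 0.41, adjusted p = 0.000365).

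The cell cycle list was higher in CD4+CD127-PD-1+ cells, with 17 of 22 genes higher and none lower (21 higher when adjusted over the list alone; mean 1.70, camera adjusted p = 1.82e-14). Its adjusted p = 0.450 with an estimated correlation. Ccnb2, a mitotic cyclin, rose by 2.41 (SE 0.39, adjusted p = 0.00302) and Cenpe, a kinetochore motor, by 2.18 (SE 0.39, adjusted p = 0.00547). Of 20 inhibitory receptor genes 7 were higher and none lower (10 over the list alone; mean 0.90, camera adjusted p = 3.76e-06, adjusted p = 0.458 with an estimated correlation). Entpd1 (ENSMUSG00000048120, chromosome 19, 40612366 to 40741602), which encodes the ectonucleotidase CD39 of chronically stimulated T cells and of macrophages, measured 74.3 ± 7.10 against 21.5 ± 3.16 CPM (1.79, SE 0.23, adjusted p = 0.00085). Nfatc1, a factor activated by calcium signals, rose by 1.06 (SE 0.13, adjusted p = 0.000641), and the exhaustion-associated Tox2 and Havcr2 by 2.73 and 1.47. Ctla4 (0.79), Tigit (0.74) and Lag3 (0.09) were not called.

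Follicular helper genes were 6 higher and 1 lower of 14 in CD4+CD127-PD-1+ cells (8 and 1 over the list alone; mean 1.16, camera adjusted p = 2.05e-06, adjusted p = 0.0740 with an estimated correlation). Il21 (ENSMUSG00000027718, chromosome 3, 37222759 to 37232636), a cytokine that helps B cells, measured 30.8 ± 6.89 against 2.03 ± 0.463 CPM (3.91, SE 0.40, adjusted p = 0.000268). Maf (ENSMUSG00000055435, chromosome 8, 115682942 to 115707794), a transcription factor of helper and regulatory cells, measured 349 ± 24.2 against 133 ± 19.6 CPM (1.39, SE 0.17, adjusted p = 0.000621). The follicular helper gene Slamf6 fell by 0.88, whereas Bcl6 (0.41) and Cxcr5 (0.97) were not called. Cebpa (2.06), also in that list, is known mainly as a myeloid factor. Cytotoxic effector genes were 10 higher and 2 lower of 25 (13 and 2 over the list alone; mean 0.71, camera adjusted p = 5.94e-05, adjusted p = 0.626 with an estimated correlation). The higher ones included the chemokine Ccl3 (2.77, SE 0.33, adjusted p = 0.000549), Ccl4 (1.80), the granzyme Gzmk (2.48) and the fractalkine receptor Cx3cr1 (4.73, SE 0.41, adjusted p = 0.000122). The lower ones were Prf1 (-2.02), which encodes perforin, and the receptor gene Klrd1 (-1.37). Nkg7, a cytotoxic granule gene, rose by 1.72 (SE 0.26, adjusted p = 0.00222). Cx3cr1 measured 74.3 ± 30.4 against 2.77 ± 0.392 CPM, while the macrophage gene Csf1r measured 222 ± 113 against 5.53 ± 2.86 CPM. Whether the higher cytotoxic list genes came from T cells or from macrophage RNA was not tested.

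The IL-7 and STAT5 list holds parts of the signalling chain and survival genes, and not only targets of the sorted receptor. It had 2 genes higher and 7 lower of 20 in CD4+CD127-PD-1+ cells (mean -0.23, camera adjusted p = 0.0425, adjusted p = 0.570 with an estimated correlation). The signalling gene Stat5b fell by 0.69, while the survival gene Bcl2l1 rose by 1.21 (SE 0.21, adjusted p = 0.0047). Foxo1, a driver of Il7r transcription that is also in the naive list, fell by 0.80 (SE 0.13, adjusted p = 0.00276). Ribosomal protein genes were 13 lower and 0 higher of 30 (20 over the list alone; mean -0.57, camera adjusted p = 1.46e-10, adjusted p = 0.581 with an estimated correlation), among them Rpl5 (-0.81, SE 0.15, adjusted p = 0.00737). Interferon-stimulated genes were 8 higher of 20 (8 and 1 lower over the list alone; mean 0.48, camera adjusted p = 0.00402, adjusted p = 0.626 with an estimated correlation), with Rtp4 at 1.27 (SE 0.22, adjusted p = 0.00462) and Rsad2 at 1.33. Of 18 cytokine genes 4 were higher, Il10 (1.81) among them (7 over the list alone; mean 0.79, camera adjusted p = 0.00205, adjusted p = 0.450 with an estimated correlation). The cytokine list passed the threshold no longer without CD4+CD127-PD-1+ replicate 2 (adjusted p = 0.145). The IL-7 and STAT5 and the interferon lists did not pass it without CD4+CD127-PD-1+ replicate 1 (adjusted p = 0.0572 and 0.0783), nor did the former without CD4+CD127+PD-1- replicate 3 (adjusted p = 0.135).

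Other lists did not pass the list test in CD4 cells, with called members as follows. Regulatory T cell genes were 2 higher and 1 lower of 17 (camera adjusted p = 0.734), with the IL-35 subunit Ebi3 at 2.35 (SE 0.49, adjusted p = 0.0108), the receptor Gpr83 at -1.74 (SE 0.38, adjusted p = 0.0141) and Foxp3 at -0.16, not called. Type 1 helper genes were 3 higher and 2 lower of 13 (adjusted p = 0.862), including Cxcr3 (0.97), the kinase gene Txk (-1.54, SE 0.13, adjusted p = 0.000122) and Il18r1 (-0.99, SE 0.23, adjusted p = 0.0175). Type 2 genes were 1 lower of 10 (Il17rb, -1.74, SE 0.38, adjusted p = 0.0131), and of 13 type 3 genes none was called (the most abundant, Rora, -0.36, adjusted p = 0.572). Tissue residency genes were 2 higher and 2 lower of 18 (adjusted p = 0.734), with P2rx7, an ATP receptor, at 1.03 (SE 0.18, adjusted p = 0.00538) and the adhesion gene Amica1 at -1.97 (SE 0.34, adjusted p = 0.00426). T cell receptor stimulation genes were 3 higher and 1 lower of 19 (adjusted p = 0.862), and chemokine receptor and integrin genes 5 higher and 4 lower of 20 (adjusted p = 0.945). Glycolysis and oxidative phosphorylation genes had 1 higher each of 16 and 18 (adjusted p = 0.193 and 0.734). These were Gapdh (0.61, SE 0.17, adjusted p = 0.0428) and Uqcrc1 (3.95, SE 0.85, adjusted p = 0.0123), a respiratory chain subunit that measured 18.7 and 552 CPM in the 2 CD4+CD127-PD-1+ libraries. Digestion stress genes were 1 higher and 3 lower of 18 (adjusted p = 0.0531), including the immediate early gene Jun (-0.86, SE 0.13, adjusted p = 0.00204). Over the list alone the higher and lower counts were 4 and 2 for regulatory, 5 and 2 for type 1, 1 and 1 for type 2, 5 and 2 for residency, 4 and 3 for receptor stimulation, 8 and 4 for chemokine receptor, 0 and 0 for glycolysis and 1 and 4 for stress genes.

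Genes of other cell types differed alongside the genes above. Of 21 myeloid genes 16 were higher in CD4+CD127-PD-1+ cells and 0 lower (17 over the list alone; mean 3.12, camera adjusted p = 4.18e-26, adjusted p = 0.108 with an estimated correlation), and the list summed to 9147 ± 5771 against 1900 ± 835 CPM. The complement gene C1qa measured 72.3 ± 31.0 against 0.714 CPM (6.63, SE 0.48, adjusted p = 5.37e-05). Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), an apolipoprotein of macrophages, measured 206 ± 70.6 against 3.31 ± 0.609 CPM (5.95, SE 0.42, adjusted p = 5.37e-05). The complement receptor C3ar1 rose by 5.70 (SE 0.38, adjusted p = 5.07e-05), the macrophage growth factor receptor Csf1r by 5.31 (SE 0.61, adjusted p = 0.00048) and the chemokine Cxcl16 by 4.23 (SE 0.47, adjusted p = 0.000365). Pan-T genes summed to 3702 ± 558 and 3688 ± 336 CPM, with 1 of 16 lower. Siglech (ENSMUSG00000051504, chromosome 7, 55768178 to 55778925), a lectin of plasmacytoid dendritic cells, was lower at 19 ± 19.2 against 274 ± 120 CPM (-3.86, SE 0.80, adjusted p = 0.0105), as was the calcium channel gene Cacna1e (-3.47, SE 0.68, adjusted p = 0.00805). Neutrophil genes were 1 higher of 10 (Csf3r, 3.87, SE 0.67, adjusted p = 0.00443; camera adjusted p = 0.0243, adjusted p = 0.824 with an estimated correlation), and their list call was absent without CD4+CD127-PD-1+ replicate 1 (adjusted p = 0.1) and with description number as a block (0.0607). None of 14 kidney tubule, 15 B and plasma cell, 11 NK and innate lymphoid or 10 CD4 lineage genes was called, and the most abundant tubule gene Umod stood at -0.87 (adjusted p = 0.696).

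Smaller lists of other cells and lineages in CD4 cells gave mixed directions without a list call. CD8 lineage genes were 3 higher and 2 lower of 15 (5 and 2 over the list alone), and gamma-delta T and NKT genes 2 higher of 7, including Tcrg-C2 (2.04, SE 0.57, adjusted p = 0.0394). Endothelial and podocyte genes were 2 higher and 1 lower of 7, the lower being Cdh5, which encodes VE-cadherin (-3.25, SE 0.73, adjusted p = 0.0149). Red cell and platelet genes were 1 higher and 1 lower of 5, with the platelet gene Pf4 at 11.2 against 0.209 CPM (5.60, SE 0.87, adjusted p = 0.00242). Mean, median and test direction differed in sign for the T cell receptor stimulation, CD8 lineage, pan-T, endothelial, B cell, NK and chemokine receptor lists.

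In the CD4 state comparison as a whole, edgeR called 1115 genes higher and 797 lower in CD127-PD-1+ cells out of 16365, and 848 and 430 of these by more than 2-fold. With 2 against 3 libraries the counts depended on single libraries. Higher calls numbered 554 without CD4+CD127-PD-1+ replicate 1, and 675 and 588 without CD4+CD127+PD-1- replicates 1 and 2. Lower calls numbered 422 and 374 without CD4+CD127-PD-1+ replicates 1 and 2, and 488 and 500 without CD4+CD127+PD-1- replicates 1 and 2. Named genes past the threshold no longer without CD4+CD127-PD-1+ replicate 1 were Ebi3 (adjusted p = 0.0662), Gpr83 (0.0518), Il18r1 (0.136), P2rx7 (0.0541), Rpl5 (0.0671) and Tcrg-C2 (0.290). Without replicate 2 they were Gpr83 (0.0931), Il17rb (0.0950), Gapdh (0.292), Uqcrc1 (0.970) and Cdh5 (0.0916). Without CD4+CD127+PD-1- replicate 1, Gapdh (0.136) and Tcrg-C2 (0.0530) were not called, without replicate 2 Gapdh (0.118), Uqcrc1 (0.0553) and Tcrg-C2 (0.107), and without replicate 3 Tcrg-C2 (0.107). By limma-voom Uqcrc1 (0.199), Cdh5 (0.0535), Tcrg-C2 (0.0628) and Csf3r (0.0515) were not called, nor Gpr83 in thinned counts (0.0683) or Gapdh in a model of the compared groups only (0.0606).

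**Figure D2:**
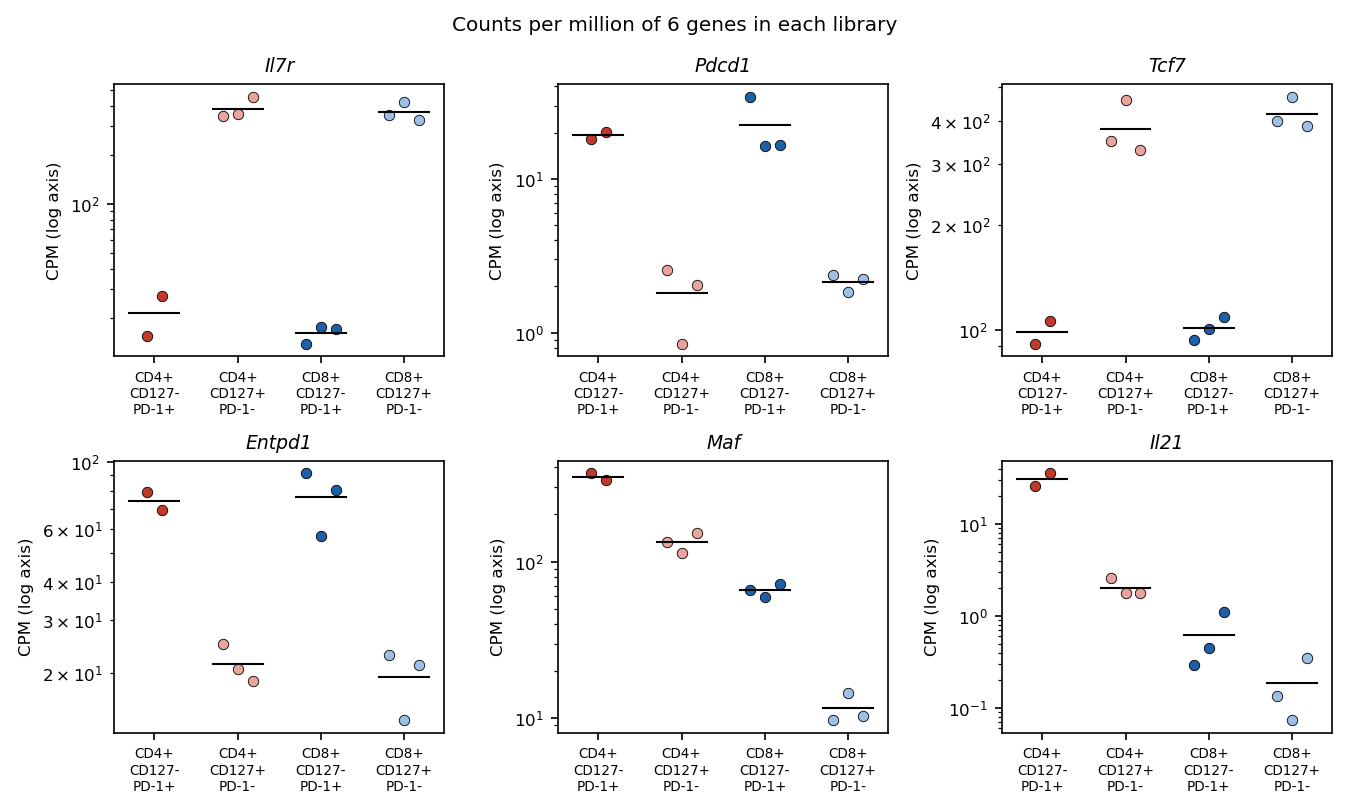
CPM of Il7r, Pdcd1, Tcf7, Entpd1, Maf and Il21 in each of the 11 libraries on a log axis, with group means as lines. Il21 averaged 30.8 CPM in CD4+CD127-PD-1+ cells and 0.619 CPM in CD8+CD127-PD-1+ cells.

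In kidney CD8 cells, 18 of 20 naive, memory and quiescence genes were lower in the CD127-PD-1+ than in the CD127+PD-1- population and 0 higher (mean -1.67, camera adjusted p = 1.88e-29). The list's adjusted p = 0.18 with an estimated correlation. Tcf7 measured 101 ± 7.70 against 418 ± 44.7 CPM (log2 fold change -2.05, SE 0.14, adjusted p = 2.12e-05) and Satb1 149 ± 40.1 against 937 ± 126 CPM (-2.65, SE 0.19, adjusted p = 2.30e-05). Igfbp4 (-3.64, SE 0.36, adjusted p = 0.000127), Rapgef4, a cyclic AMP exchange factor (-2.97, SE 0.41, adjusted p = 0.00073), and the egress receptor S1pr1 (-1.45, SE 0.18, adjusted p = 0.000394) were lower too. So was the gut homing receptor Ccr9, which plasmacytoid dendritic cells also carry (-3.24, SE 0.47, adjusted p = 0.000995).

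Inhibitory receptor genes were 11 higher and 0 lower of 20 in CD8+CD127-PD-1+ cells (14 over the list alone; mean 1.24, camera adjusted p = 4.94e-09, adjusted p = 0.376 with an estimated correlation). Entpd1 measured 76.2 ± 17.8 against 19.4 ± 4.78 CPM (1.97, SE 0.22, adjusted p = 0.000205). Lilrb4, an inhibitory receptor of T cells and macrophages, rose by 2.73 (SE 0.38, adjusted p = 0.000733). Tox2 (3.61), Havcr2 (1.63), Tox (1.56), Tigit (1.46) and Ctla4 (1.26) rose as well, while Lag3 (1.02) and Cd160 (0.28) were not called. Follicular helper list genes were 6 higher and 1 lower of 14 (7 and 2 over the list alone; mean 0.96, camera adjusted p = 2.76e-04, adjusted p = 0.185 with an estimated correlation). Maf measured 65.8 ± 6.33 against 11.6 ± 2.65 CPM (2.51, SE 0.17, adjusted p = 1.95e-05), Asb2, a ubiquitin ligase adaptor, rose by 2.24 (SE 0.27, adjusted p = 0.000334), and Bcl6 by 1.25. Il21 measured 0.619 ± 0.438 and 0.185 ± 0.143 CPM in the CD8 populations and was not called. The regulatory cytokine Il10 rose by 2.68 and the residency factor Prdm1 by 1.45 (SE 0.24, adjusted p = 0.00204).

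Cytotoxic effector genes were 6 higher and 1 lower of 25 in CD8+CD127-PD-1+ cells (mean 0.43, camera adjusted p = 0.0155, adjusted p = 0.933 with an estimated correlation). Higher were Ccl3 (2.14, SE 0.29, adjusted p = 0.00073), Cx3cr1 (2.06, SE 0.33, adjusted p = 0.00181), Ccl4 (1.18) and the transcription factor Zeb2 (1.44), and lower was Klrd1 (-0.88, SE 0.24, adjusted p = 0.0315). The killing genes Prf1 (-0.02), Gzma (-0.43), Gzmb (0.51) and Ifng (0.50) were not called. That list did not pass without CD8+CD127-PD-1+ replicate 1 or 2 (adjusted p = 0.0586 and 0.0832) or without CD8+CD127+PD-1- replicate 2 (adjusted p = 0.310). Whether its higher members came from T cells or from macrophage RNA was not tested. Cell cycle genes were 5 higher of 22 (16 over the list alone; mean 0.97, camera adjusted p = 1.27e-06, adjusted p = 0.628 with an estimated correlation), with Cenpe at 1.34 (SE 0.35, adjusted p = 0.0238), the replication gene Mcm5 at 1.15 (SE 0.31, adjusted p = 0.0278) and Mki67 at 1.04, not called. The cell cycle list summed to 1999.5 CPM in CD8+CD127+PD-1- replicate 3 against 861.7 and 732.5 CPM in replicates 1 and 2, and its mean change was 1.53 without replicate 3. Interferon-stimulated genes were 8 higher of 20 (12 and 1 lower over the list alone; mean 0.63, camera adjusted p = 5.42e-04, adjusted p = 0.601 with an estimated correlation), among them Oas1a (2.24, SE 0.27, adjusted p = 0.000342) and Rsad2 (2.03).

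The IL-7 and STAT5 list had 1 gene higher and 6 lower of 20 in CD8+CD127-PD-1+ cells (mean -0.31, camera adjusted p = 0.00636, adjusted p = 0.376 with an estimated correlation). Lower were the kinase gene Pim2 (-1.90, SE 0.21, adjusted p = 0.000214), Jak1, a kinase bound to the IL-7 receptor complex (-0.53, SE 0.08, adjusted p = 0.00146), and Stat5b (-0.58). The list missed the threshold without CD8+CD127+PD-1- replicate 3 (adjusted p = 0.0549). Ribosomal protein genes were 26 lower of 30 (29 over the list alone; mean -0.76, camera adjusted p = 1.63e-17, adjusted p = 0.376 with an estimated correlation), with Rpl4 at 874 ± 16 against 1365 ± 38.9 CPM (-0.64, SE 0.09, adjusted p = 0.000995). With library totals as the only scaling, the median of all genes moved to -0.23 in this comparison and these directions held.

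Lists without a list call in CD8 cells held these called members. Regulatory T cell genes were 5 higher and 3 lower of 17 (camera adjusted p = 0.444), with Ebi3 at 3.2 (SE 0.50, adjusted p = 0.00145) and Gpr83 at -4.10 (SE 0.43, adjusted p = 0.00018). Tissue residency genes were 6 higher and 1 lower of 18 (adjusted p = 0.147), including P2rx7 (0.87, SE 0.17, adjusted p = 0.00565). Type 1 genes were 2 higher and 1 lower of 13 (adjusted p = 0.873), with the inflammatory cytokine Tnf at 0.96 (SE 0.16, adjusted p = 0.00207) and Txk at -1.59 (SE 0.11, adjusted p = 2.30e-05). Type 2 genes were 2 higher and 1 lower of 10 (adjusted p = 0.959; Il17rb -1.96, SE 0.37, adjusted p = 0.00436), and type 3 genes 3 higher of 13 (adjusted p = 0.866; Tmem176a 2.64, SE 0.36, adjusted p = 0.000654). T cell receptor stimulation genes were 3 higher and 2 lower of 19 (adjusted p = 0.898), with the early growth response gene Egr2 at 1.12 (SE 0.14, adjusted p = 0.000411). Cytokine genes were 3 higher and 1 lower of 18 (adjusted p = 0.714; Tnfsf8, a CD30 ligand, -2.39, SE 0.41, adjusted p = 0.00236), and chemokine receptor and integrin genes 5 higher and 4 lower of 20 (adjusted p = 0.808). Glycolysis genes were 3 higher of 16 (adjusted p = 0.0577; hexokinase Hk2 1.61, SE 0.31, adjusted p = 0.00486), and of 18 oxidative phosphorylation genes none was called (Sdha -0.04, adjusted p = 0.802). Digestion stress genes were 2 higher and 3 lower of 18 (adjusted p = 0.714), with Atf3 at 2.00 (SE 0.29, adjusted p = 0.000918). Over the list alone the higher and lower counts were 6 and 3 for regulatory, 7 and 1 for residency, 3 and 3 for type 1, 2 and 2 for type 2, 5 and 3 for receptor stimulation, 5 and 3 for cytokine and 7 and 5 for chemokine receptor genes. Mean, median and test direction differed in sign for the type 1, type 2, type 3, oxidative phosphorylation, cytokine, chemokine receptor and stress lists.

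Myeloid genes were 16 higher and 0 lower of 21 in CD8+CD127-PD-1+ cells beside the genes above (mean 3.16, camera adjusted p = 5.91e-26, adjusted p = 0.18 with an estimated correlation), summing to 11655 ± 2535 against 2552 ± 1645 CPM. The complement gene C1qa measured 66.7 ± 27.3 against 0.541 CPM (6.93, SE 0.47, adjusted p = 1.95e-05). The 5 largest increases under the abundance and no-overlap rule were C3ar1 (5.86, SE 0.38, adjusted p = 1.62e-05), Csf1r (4.99, SE 0.58, adjusted p = 0.000294), Apoe (4.88, SE 0.38, adjusted p = 3.20e-05), the receptor kinase Axl (4.19, SE 0.37, adjusted p = 7.66e-05) and lysozyme Lyz2 (4.18, SE 0.53, adjusted p = 0.000437). B and plasma cell genes were 6 higher of 15 (14 over the list alone; mean 2.03, camera adjusted p = 5.77e-05, adjusted p = 0.601 with an estimated correlation), including Ms4a1 (2.78), Cd79a (2.59) and the antibody light chain Igkc (1.98, SE 0.48, adjusted p = 0.0168). Neutrophil genes were 7 higher of 10 (10 over the list alone; mean 3.96, camera adjusted p = 3.18e-06, adjusted p = 0.376 with an estimated correlation), with Csf3r at 4.62 (SE 0.61, adjusted p = 0.000597), and summed to 232 ± 162 CPM. Siglech measured 11 ± 7.86 against 177 ± 98.4 CPM (-4.01, SE 0.69, adjusted p = 0.00251). Pan-T genes summed to 3272 ± 559 and 3479 ± 405 CPM, with 1 of 16 lower. No kidney tubule gene of 14 was called (Umod -2.04, adjusted p = 0.216). Endothelial genes were 1 lower of 7 (Cdh5 -3.38, SE 0.63, adjusted p = 0.0041), NK genes 1 higher of 11 (Ncr1 1.98, SE 0.51, adjusted p = 0.0222) and gamma-delta T and NKT genes 2 higher and 1 lower of 7 (Zbtb16, which encodes PLZF, 2.99, SE 0.53, adjusted p = 0.00319). Red cell and platelet genes were 1 higher of 5 (1 and 1 lower over the list alone; Pf4, 7.05 against 0.256 CPM, 4.73, SE 0.80, adjusted p = 0.00235), CD4 lineage genes 2 higher and 1 lower of 10 (2 and 2 over the list alone), and CD8 lineage genes 1 lower of 15 (0 over the list alone).

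**Figure D3:**
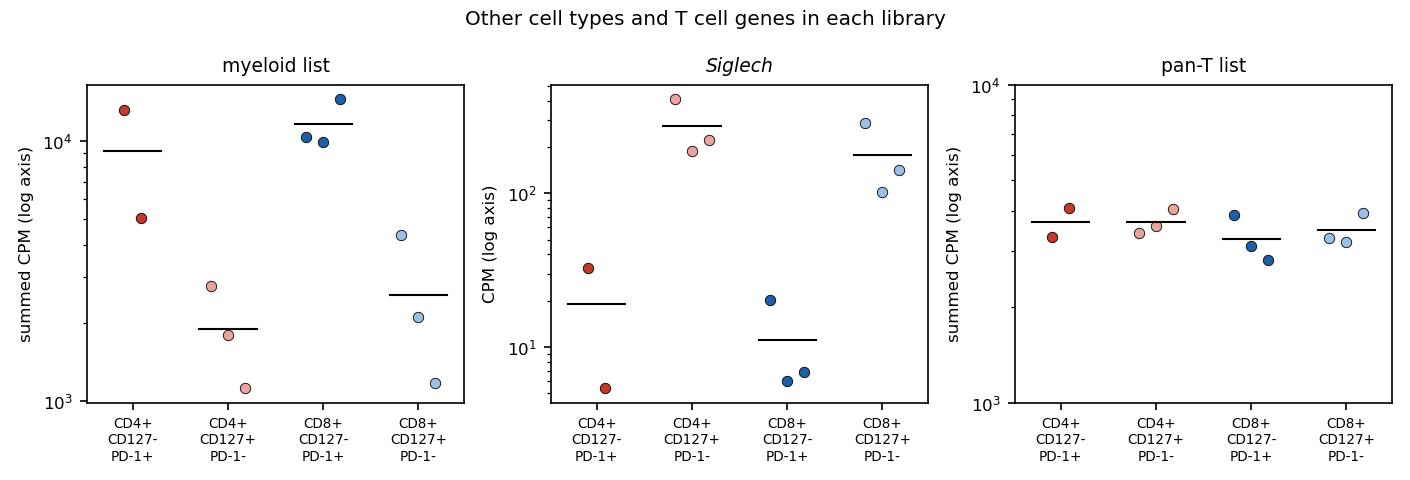
Summed CPM of the myeloid list, CPM of Siglech and summed CPM of the pan-T list in each library on log axes, with group means as lines. The myeloid list averaged 9147 CPM in the CD127-PD-1+ and 1900 CPM in the CD127+PD-1- sort of CD4 cells, and 11655 and 2552 CPM in those of CD8 cells.

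In the CD8 state comparison edgeR called 1481 genes higher and 1074 lower, 1052 and 506 of them by more than 2-fold. With library totals as the only scaling the counts were 1069 higher and 2605 lower, so the share of calls that were higher went from 58.0% to 29.1% and the majority direction depends on the scaling. Higher calls numbered 861 without CD8+CD127-PD-1+ replicate 3 and 929 without CD8+CD127+PD-1- replicate 2. Lower calls numbered 696 and 614 without CD8+CD127-PD-1+ replicates 2 and 3, and 638 without CD8+CD127+PD-1- replicate 2. Named genes past the threshold no longer were Klrd1 without CD8+CD127-PD-1+ replicate 1 (adjusted p = 0.0934), replicate 3 (0.124) or CD8+CD127+PD-1- replicate 3 (0.0956). Cenpe and Mcm5 were lost without CD8+CD127-PD-1+ replicate 2 (0.0572 and 0.0961) or 3 (0.0813 and 0.0839) and without CD8+CD127+PD-1- replicate 1 (0.0810 and 0.0973) or 2 (0.0855 and 0.101). Igkc was lost without CD8+CD127-PD-1+ replicate 2 (0.0514) or CD8+CD127+PD-1- replicate 1 (0.0632). Ncr1 was lost without CD8+CD127-PD-1+ replicate 3 (0.101) and without CD8+CD127+PD-1- replicate 1 (0.0766) or 2 (0.0719). With description number as a block Klrd1 (0.122) and Ncr1 (0.0661) were not called, nor Pf4 by limma-voom (0.0632).

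The CD4 and CD8 state changes overlapped. Of the 1115 genes higher in CD4+CD127-PD-1+ cells, 744 (66.7%) were also higher in CD8+CD127-PD-1+ cells against 101 expected (odds ratio 39.4), and 0 were lower there. Of the 797 lower genes, 534 (67.0%) were also lower in CD8 cells against 52.3 expected (odds ratio 56.4), and 1 was higher. These shared calls include Tcf7, Satb1, Entpd1, Maf, Ccl3, Apoe and Siglech. They are not of T cell genes alone, since 16 of 21 myeloid genes were higher in each comparison. With a myeloid score of each library as a covariate, added after the data were seen, shared calls numbered 125 higher and 200 lower. That score hardly separates myeloid RNA from the sorted state, so the part of the overlap due to T cells cannot be told. Fold changes of the CD4 and CD8 comparisons correlated with r = 0.718 over all genes and r = 0.836 over the 3188 genes called in either, of which 95.9% had the same sign. Genes are not independent replicates, so these values describe the present libraries. Shared higher calls numbered 363 without CD4+CD127-PD-1+ replicate 1 and 453 without CD4+CD127+PD-1- replicate 2, and shared lower calls 313 and 289 without CD4+CD127-PD-1+ replicates 1 and 2.

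**Figure D4:**
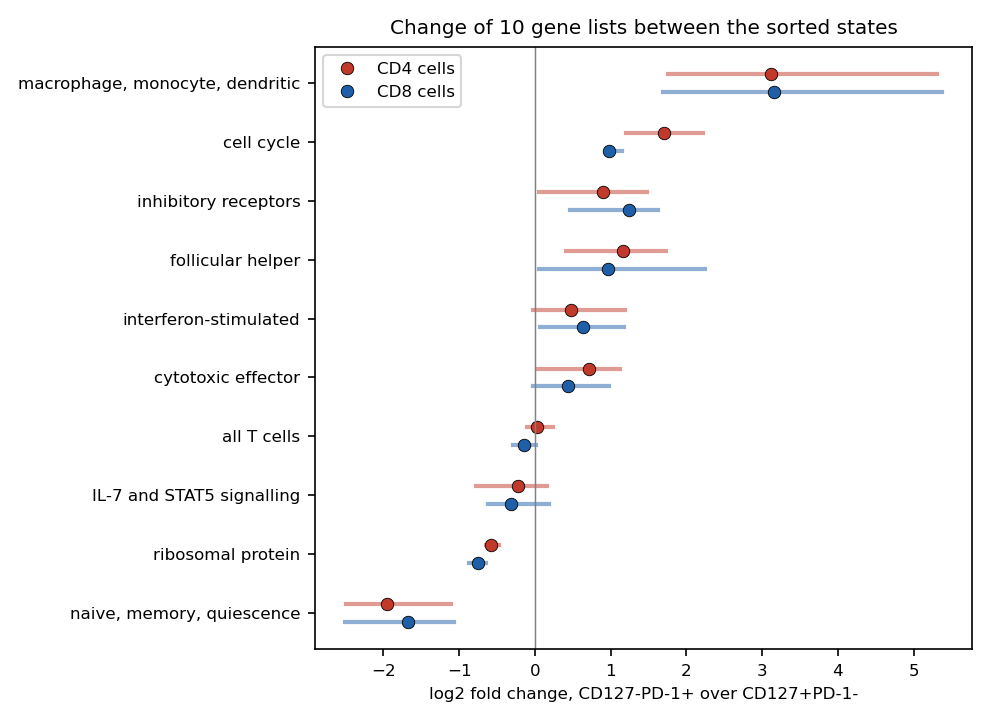
Mean log2 fold change (dots) and interquartile range over members (bars) of 10 gene lists in the CD4 and CD8 state comparisons. The naive, memory and quiescence list averaged -1.95 and -1.67, and the myeloid list 3.12 and 3.16.

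With a myeloid score of each library as a covariate, an alternative added after the data were seen, 316 genes were higher and 374 lower in the CD4 and 133 higher and 242 lower in the CD8 state comparison. Every CD127-PD-1+ library had a higher score than every CD127+PD-1- library, so this covariate hardly separates myeloid RNA from the sorted state. The follicular helper (adjusted p = 0.214 and 0.293 in CD4 and CD8 cells), interferon (0.345 and 0.224) and ribosomal protein lists (0.820 and 0.365) were not past the threshold with it. The mean of the IL-7 and STAT5 list changed sign to 0.21 and 0.16 (adjusted p = 0.25 and 0.395). The pan-T list also moved, to 1.0 and 0.89, so the covariate shifted genes of all T cells as well as myeloid ones.

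The state change of Nt5e differed between CD4 and CD8 cells. Nt5e (ENSMUSG00000032420, chromosome 9, 88327197 to 88372092) encodes CD73, which makes adenosine from the AMP that CD39 produces. It measured 17.7 ± 2.06 CPM in CD8+CD127-PD-1+ against 73.6 ± 9.70 CPM in CD8+CD127+PD-1- cells (log2 fold change -2.06, SE 0.16, adjusted p = 3.20e-05). In CD4 cells it measured 65.7 ± 4.70 and 71.0 ± 13.1 CPM (-0.11, adjusted p = 0.741), and the state-by-lineage difference was 1.94 (SE 0.23, adjusted p = 0.0406). Nt5e was the only gene higher in that test by edgeR, with 0 lower. Limma-voom also gave 1 and 0, and DESeq2 20 and 40. By edgeR 897 of 16365 genes had an unadjusted p under 0.05, little above the share of 0.05 that arises without any difference. Nt5e was not called with replicate number as a block (adjusted p = 0.234 by description and 0.101 by title). Nor was it called without CD4+CD127-PD-1+ replicate 2 (0.18), CD4+CD127+PD-1- replicates 1 or 2 (0.121 and 0.228), CD8+CD127-PD-1+ replicates 2 or 3 (0.136 and 0.215) or CD8+CD127+PD-1- replicates 1 or 2 (0.18 and 0.146). Cd8b1, whose interaction value was -3.05 (adjusted p = 0.313), was called by DESeq2 (adjusted p = 0.0210). Nkg7 stood at 1.22 (adjusted p = 0.676).

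Of the 30 lists, 5 passed the camera test for state by lineage, with 0 members called in each (1 higher and 1 lower cytokine gene over the list alone) and all with adjusted p = 0.848 with an estimated correlation. Cell cycle genes rose more in CD4 cells (mean difference 0.73, camera adjusted p = 4.0e-04), cytokine genes differed by a mean of 0.87 (adjusted p = 0.00491) and ribosomal protein genes by 0.18 (adjusted p = 0.0162). B and plasma cell genes (-1.84, adjusted p = 1.0e-10) and neutrophil genes (-2.07, adjusted p = 7.94e-04) differed towards CD8 cells. The cell cycle list was lost without CD4+CD127-PD-1+ replicate 2 (adjusted p = 0.767) or CD8+CD127+PD-1- replicate 3 (0.503), the cytokine list without CD4+CD127-PD-1+ replicate 2 (0.171) or CD4+CD127+PD-1- replicate 2 (0.110), and the neutrophil list without CD4+CD127-PD-1+ replicate 2 (0.171). The ribosomal protein list was lost without CD4+CD127+PD-1- replicates 1 or 3 (0.549 and 0.0695), CD8+CD127-PD-1+ replicates 1 or 3 (0.0935 and 0.273) or CD8+CD127+PD-1- replicate 1 (0.0696), and with description number as a block (0.768). Library totals as the only scaling moved the median of all genes to 0.24 in this test. The naive, inhibitory, follicular helper, interferon and myeloid lists did not pass it, so no lineage difference in their state change was found.

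CD4 and CD8 cells of the CD127+PD-1- state differed in helper, regulatory and cytotoxic genes. Cd40lg (ENSMUSG00000031132, chromosome X, 57212143 to 57224042), the helper ligand CD154, measured 134 ± 24.0 against 4.75 ± 0.924 CPM (log2 fold change 4.82, SE 0.23, adjusted p = 1.41e-06). Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), the regulatory T cell factor, measured 73.7 ± 22.5 CPM in CD4 cells (5.29, SE 0.33, adjusted p = 8.20e-06), with Lrrc32, which anchors latent TGF-beta on regulatory cells, at 3.58 (SE 0.25, adjusted p = 1.87e-05). Maf (3.52, SE 0.17, adjusted p = 1.41e-06), the type 2 cytokine Il4 (5.64, SE 0.69, adjusted p = 0.00086) and the carboxypeptidase Cpd (3.25, SE 0.34, adjusted p = 0.000339) were higher in CD4 cells. Eomes (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132), a factor of memory CD8 cells, measured 49.4 ± 6.79 CPM in CD8 cells (-5.50, SE 0.39, adjusted p = 1.87e-05). The granzymes Gzmk (-4.77, SE 0.51, adjusted p = 0.000393) and Gzma (-4.69, SE 0.66, adjusted p = 0.00185), the adhesion gene Crtam (-3.74, SE 0.30, adjusted p = 4.97e-05), Bend4 (-3.98, SE 0.27, adjusted p = 1.45e-05), Nkg7 (-2.57, SE 0.25, adjusted p = 0.000175) and the granule inhibitor Cst7 (-1.99, SE 0.18, adjusted p = 0.000107) were higher in CD8 cells. Cd4 (6.40, SE 0.53, adjusted p = 5.36e-05) and Cd8a (-9.03, SE 0.46, adjusted p = 1.41e-06) differed by the sort.

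Part of the genes above were taken from the lists, so the lists are not separate support for them. The lists also share members, so their results are not independent of each other. For example, Gzmk, Prf1 and Nkg7 stand in the CD8 lineage and cytotoxic lists. Foxp3 stands in the CD4 lineage and regulatory lists, and Il4 in the follicular helper, type 2 and cytokine lists. In the CD127+PD-1- state 9 of the 15 lists past the camera test also passed with an estimated correlation. Higher in CD4 cells were CD4 lineage (8 of 10 genes, adjusted p = 0.00157 with an estimated correlation), regulatory T cell (13 of 17, 0.00237), follicular helper (7 higher and 1 lower of 14, 0.00422), type 2 (8 of 10, 1.98e-04), type 3 (10 of 13, 0.0122), cytokine (10 of 18, 0.0037) and T cell receptor stimulation genes (4 higher and 2 lower of 19, 0.0452). Lower were CD8 lineage (13 of 15, 0.00422) and cytotoxic effector genes (16 of 25, 0.0416). The receptor stimulation list had a median of 0.39. Its largest value, 4.82, was that of Cd40lg, which also stands in the CD4 lineage and cytokine lists. Over the list alone the higher and lower counts were 13 and 1 for regulatory, 8 and 1 for follicular helper, 12 and 0 for type 3, 11 and 0 for cytokine, 9 and 3 for receptor stimulation, 0 and 14 for CD8 lineage and 0 and 17 for cytotoxic genes. The other 6 lists, which were tissue residency, cell cycle, oxidative phosphorylation, ribosomal protein, tubule and stress, had an adjusted p from 0.441 to 0.632 with an estimated correlation. Cell cycle genes averaged -1.0 with 1 called lower (13 over the list alone), and -0.44 without CD8+CD127+PD-1- replicate 3. In total edgeR called 452 genes higher and 271 lower in CD4 cells. Without CD4+CD127+PD-1- replicate 1 the counts were 255 and 140, without replicate 3 they were 235 and 143, and without CD8+CD127+PD-1- replicate 1 the lower calls numbered 177. With description number as a block the counts were 634 and 436. After group means were removed, same-number pairs of these CD4 and CD8 libraries correlated at 0.2085, 0.1473 and 0.3178, so the unpaired counts may leave out a shared pool.

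CD4 and CD8 cells of the CD127-PD-1+ state also differed in helper, regulatory and cytotoxic genes. Il21 measured 30.8 ± 6.89 against 0.619 ± 0.438 CPM (log2 fold change 5.62, SE 0.44, adjusted p = 4.66e-05). Cd40lg (5.32, SE 0.25, adjusted p = 2.09e-06), Foxp3 (6.09, SE 0.37, adjusted p = 1.12e-05), Lrrc32 (3.98, SE 0.28, adjusted p = 3.08e-05), Maf (2.41, SE 0.17, adjusted p = 3.08e-05), Tnfsf8 (3.08, SE 0.44, adjusted p = 0.0031) and the matrix gene Podnl1 (3.65, SE 0.27, adjusted p = 3.09e-05) were higher in CD4 cells. Eomes (-5.05, SE 0.44, adjusted p = 9.55e-05), Prf1 (-4.36, SE 0.40, adjusted p = 0.000124), Klrd1 (-2.76, SE 0.31, adjusted p = 0.000785), Gzma (-4.24, SE 0.77, adjusted p = 0.0143) and Gzmk (-3.27, SE 0.52, adjusted p = 0.00622) were higher in CD8 cells. Gzma was not called without CD4+CD127-PD-1+ replicate 1 or 2 (adjusted p = 0.0960 and 0.128) or with sample weights in limma-voom (adjusted p = 0.0550), nor Gzmk without replicate 2 (0.0831). The sort markers Cd4 (7.02, SE 0.56, adjusted p = 4.66e-05), Cd8a (-10.49, SE 0.60, adjusted p = 9.00e-06) and Cd8b1 (-6.50, SE 0.57, adjusted p = 9.55e-05) differed by the sort.

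The lists share members here as in the CD127+PD-1- state, so their results are not independent of each other. Of the 18 lists past the camera test in the CD127-PD-1+ state, 7 also passed with an estimated correlation. These were CD4 lineage (9 of 10 higher in CD4 cells, adjusted p = 4.53e-04 with an estimated correlation), regulatory T cell (11 of 17, 6.99e-04), follicular helper (6 of 14, 0.00102), type 2 (8 of 10, 9.77e-05), type 3 (8 of 13, 0.0209), cytokine (11 of 18, 6.99e-04) and CD8 lineage genes (12 of 15 lower, 0.00386). Over the list alone the higher and lower counts were 14 and 1 for regulatory, 7 and 1 for follicular helper, 9 and 0 each for type 2 and type 3, 15 and 0 for cytokine and 0 and 14 for CD8 lineage genes. Cytotoxic effector genes were 11 lower of 25 (17 over the list alone, adjusted p = 0.0778 with an estimated correlation). The other 11 lists, counting this one, had an adjusted p from 0.0778 to 0.785 with an estimated correlation. Among them were lists of other cells that were lower in CD4 cells, beside these helper and cytotoxic genes. They were the B and plasma cell (1 of 15 called lower and 3 over the list alone, camera adjusted p = 5.75e-09, 0.219 with an estimated correlation), neutrophil (2 of 10 lower, 8 lower and 1 higher over the list alone, 4.28e-04 and 0.388), NK (1 lower and 2 higher of 11, 4 and 2 over the list alone, 0.00601 and 0.219) and myeloid lists (0 of 21 called, 1 lower over the list alone, 0.0293 and 0.739). Without CD4+CD127-PD-1+ replicate 2 the NK list was not past the threshold, nor was the myeloid list without CD8+CD127-PD-1+ replicates 2 or 3 (adjusted p = 0.0639 and 0.197). With description number as a block neither the NK nor the myeloid list passed. The test direction of the myeloid list also depended on which CD4+CD127-PD-1+ library was left out. Mitochondrial ribosomal RNA made up 30.8% of counts in these CD4 and 38.9% in these CD8 libraries. In total edgeR called 262 genes higher and 138 lower in CD4 cells. Without CD4+CD127-PD-1+ replicate 2 the counts were 96 and 30, and without CD8+CD127-PD-1+ replicates 2 and 3 they were 120 and 69, and 130 and 68. With library totals as the only scaling the median of all genes moved to 0.23 and the calls to 721 higher and 114 lower. DESeq2 gave 425 and 292, no filter 443 and 348, and a model of the compared groups only 143 and 71.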

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

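No test in this part was chosen after its result was seen, since the state-by-lineage test, its lists and the replicate blocks were planned. Each result below is a difference between the CD4 and the CD8 state change. Nt5e, which encodes CD73, differed by 1.94 (SE 0.23, adjusted p = 0.0406), with a decrease of 2.06 in CD8 cells and no called change in CD4 cells. Cell cycle genes differed by a mean of 0.73 towards CD4 cells, where their state change averaged 1.70 against 0.97. Ribosomal protein genes differed by 0.18, being lower by 0.57 in CD4 and 0.76 in CD8 cells. Cytokine genes differed by 0.87, a mean that includes Il17a, which had no counts in CD8+CD127-PD-1+ cells, with a median of 0.45. B and plasma cell genes differed by -1.84, and the list was called higher in CD8+CD127-PD-1+ cells (adjusted p = 0.601 with an estimated correlation) but not in the CD4 state comparison. Neutrophil genes differed by -2.07, with 7 of 10 called higher in CD8 and 1 of 10 in CD4 cells.

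Against a firm reading of Nt5e stands its loss with replicate number as a block (adjusted p = 0.234 by description number) and without 7 of the 11 libraries. The 5 lists had no called member each and an adjusted p = 0.848 with an estimated correlation. What causes the Nt5e difference, and whether it holds with more CD4+CD127-PD-1+ pools, stays open.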

How the results depend on the processing

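Scaling without ribosomal RNA and mitochondrial genes and the myeloid covariate were chosen only after results were seen, and all other alternatives were planned. Of 143 named-gene results 118 passed the threshold and 100 of these did so without each library in turn. The myeloid covariate ended 48 of the 118 and also turned the sign of 3 others, which it left uncalled, and sample weights ended 4 (Uqcrc1, Cdh5, Tcrg-C2 and Gzma). Of 150 list results 60 passed, 16 of them with an estimated correlation, and fry ended 27. The myeloid covariate ended 14 list calls, added 16 and turned the test direction of 14 others. The limits are n = 2 in CD4+CD127-PD-1+ cells and pools instead of animals. Replicate numbers were not used as pairs in the main model, which was fixed before the data were examined, and the labels name no batch. In the data, not every pair correlated above 0.1. Neither point excludes that libraries of a number came from the same pools, which the sources do not give. By description 10 of 12 pairs correlated above 0.1 (lowest 0.001, median 0.153). Of 10 libraries, 8 correlated best with a library of their own number, a hint that libraries of a number share something. By title the median was 0.001 over 15 pairs and 6 of 11 correlated best. The block by title ended 2 of the named calls, Nt5e among them. Leaving out mitochondrial, haemoglobin and immunoglobulin genes ended 1. The block by description ended 3 of the named calls (Klrd1, Ncr1 and Nt5e) and 6 list calls. These were neutrophil genes in the CD4 state (adjusted p = 0.0607), ribosomal protein genes in state by lineage (0.768) and, for CD4 against CD8 in CD127-PD-1+ cells, cell cycle (0.094), IL-7 and STAT5 (0.0958), myeloid (0.129) and NK genes (0.0958). The causes of the changes below were not tested, except that a stricter threshold lowers counts by construction.

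Counts of genes are given higher/lower. At an adjusted p under 0.01 they were 404/269 and 683/465 in the CD4 and CD8 state comparisons, 216/106 and 97/40 for CD4 against CD8 in the CD127+PD-1- and CD127-PD-1+ states, 0/0 for state by lineage, and 290/191 shared. With library totals only, 1069/2605 were called in the CD8 state comparison and 721/114 for CD4 against CD8 in CD127-PD-1+ cells. Without a filter the CD127+PD-1- lineage comparison gave 578 lower, CD127-PD-1+ 443/348 and state by lineage 27/58, and DESeq2 gave 527 lower, 425/292 and 20/40. Sample weights gave 485 lower in the CD4 state comparison and 66 lower for CD127-PD-1+, where compared groups only gave 143/71. The block by description gave 436 lower for CD127+PD-1- and 0/1 for state by lineage, the block by title 0 higher. With the myeloid covariate the CD4 state gave 316/374, the CD8 state 133/242, CD127+PD-1- 455 lower, state by lineage 2/3 and shared calls 125/200.

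Leaving out each library in turn gave 554 to 804 higher and 374 to 582 lower in the CD4 state, 861 to 1495 and 614 to 1026 in the CD8 state, 235 to 419 and 140 to 268 for CD127+PD-1-, 96 to 244 and 30 to 140 for CD127-PD-1+, 0 to 2 and 0 to 4 for state by lineage, and 363 to 901 and 289 to 522 shared. The test direction of 5 lists depended on a CD4+CD127-PD-1+ library. For CD4 against CD8 in CD127-PD-1+ cells the means ran from -0.77 to 0.0757 for cell cycle, -0.38 to 0.21 for glycolysis and -0.51 to 0.28 for oxidative phosphorylation genes, each highest without replicate 1 and lowest without replicate 2. Myeloid genes in that comparison ran from -1.13 without replicate 1 to -0.061 without replicate 2, and ribosomal protein genes in state by lineage from 0.40 to -0.0818.

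With the myeloid covariate the test direction changed, with values or means in parentheses, in the CD4 state for Csf3r (-0.12) and the type 3 (1.58), IL-7 and STAT5 (0.21), pan-T (1.0), myeloid (-0.0477) and neutrophil lists (-1.92). In the CD8 state it changed for Ncr1 (-1.01), Atf3 (-0.0324) and the type 1 (0.95), IL-7 and STAT5 (0.16), oxidative phosphorylation (1.0), CD4 lineage (0.80), CD8 lineage (0.80), pan-T (0.89), myeloid (-0.0733) and B and plasma cell lists (-2.37). For CD4 against CD8 in CD127-PD-1+ cells it changed for myeloid genes (-0.0445).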

Other observations

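The 7 tests printed in this part were fixed in wording before their values were computed, except that the tubule comparison, the myeloid covariate and the test of a general contaminating share were chosen only after the results they address were seen.

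Macrophage genes were higher in both CD127-PD-1+ sorts, and macrophages or their RNA in those sorts may be the source, with Csf1r at 222 ± 113 and 211 ± 86.4 CPM in the CD4 and CD8 sorts and Apoe at 206 ± 70.6 and 154 ± 54.4 CPM. Of 11 measured macrophage genes not looked at before, 7 were higher in CD4 and 8 in CD8 cells (medians 1.447 and 1.576), among them Mertk and Lgmn, while Ctsl was lower in both. They were chosen after other macrophage genes had been seen to rise in these libraries, so a rise was likely beforehand. The CD4 median was the value of Cd163, which was not called (adjusted p = 0.318) at 5.04 and 1.04 CPM in the CD4+CD127-PD-1+ libraries. Of genes seen beforehand 19 of 19 were higher, which is not independent evidence. Against a mere drop in T cell share that raises every other cell type, the myeloid list exceeded the tubule list by at least 3.513. Its SE of 0.688 is over genes and not over libraries, and tubule genes were near the floor. In the CD8 state comparison neutrophil (mean 3.96) and B and plasma cell genes (2.03) rose as well, while endothelial and red cell lists averaged -0.84 and -0.41. In the CD4 state comparison the neutrophil and B and plasma cell means were 1.88 and 0.19. A shared rise of several immune cell types was not tested. A gate on CD4 or CD8 at the cell surface would remove macrophages that carry neither, the labels name no further lineage gate, and a change in the T cells' own expression was not tested. Of the 21 myeloid list genes, 13 measured at least 10 CPM in both CD127+PD-1- sorts as well, and 0 stand in another list.

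The inhibitory receptor list was higher in both CD127-PD-1+ sorts by camera (adjusted p = 0.458 and 0.376 with an estimated correlation), and macrophage RNA could be part of it, since macrophages also express Entpd1 and Lilrb4. With the myeloid score as a covariate the list stayed higher, with a larger adjusted p of 0.0002363 over both comparisons (4.408e-06 in the other). Its mean moved from 0.90 to 1.31 in CD4 and from 1.24 to 1.69 in CD8 cells, but its called members fell from 7 to 4 and from 11 to 3, and the pan-T list moved further, from 0.03 to 1.0 and from -0.14 to 0.89. Every CD127-PD-1+ library had a higher score than every CD127+PD-1- library, so the score nearly stands for the state and this test decides nothing. Macrophage RNA as the whole cause and a change in T cells cannot be told apart for this list.

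Plasmacytoid dendritic cell genes were lower in both CD127-PD-1+ sorts, and such cells or their RNA in the CD127+PD-1- sorts may be the source, with Siglech at 274 ± 120 and 177 ± 98.4 CPM in the CD4 and CD8 sorts. Of 10 genes of these cells not looked at before, 6 were lower in CD4 cells and 5 lower and 1 higher in CD8 cells (medians -2.208 and -1.421). They were chosen after other genes of these cells had been seen to fall in these libraries, so a fall was likely beforehand. Cd300c and Smim5 fell in both, Tlr9 rose by 1.42 in CD8 cells, and Havcr1 and Atp1b1 are also kidney tubule genes. A general share of contaminating cells would have lowered the myeloid list too, whose mean was at least 3.123 (SE 0.492). That SE is over genes and not over libraries, and the genes moved together (estimated correlation 0.55 in the CD4 state comparison), so it is too small. A gate on CD8 would remove plasmacytoid dendritic cells unless they carry CD8, while in mice these cells can carry CD4. Of 19 genes seen beforehand, which are not independent evidence, 9 and 8 were lower and 5 stand in another list, and 12 measured at least 10 CPM in both CD127-PD-1+ sorts.

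Regrouping the libraries left few alternatives. Of the 10 ways to split the 6 CD8 libraries 3 against 3, 1 gave as many as 2555 called genes, which was the sorted grouping, and the highest other split gave 0. The 6 CD127+PD-1- libraries gave 1 of 10 likewise, with 723 called genes and 0 in the highest other split. With 10 splits a share under 0.05 cannot be reached. Every other split also put libraries of both sorted populations on each side, so few or no calls were likely beforehand.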
